A study of Mus musculus with 3 samples.

How the data were processed

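Blood leukocytes of C57/BL6J mice were measured by droplet single-cell RNA sequencing in 3 libraries. Per the labels, 1 library was made for each of 3 groups, a control group (Con, 0 h), a group after 24 h of sleep deprivation (SD24h) and a group after 48 h (SD48h), each from the pooled leukocytes of 3 mice, after red cell lysis and with about 7000 cells planned per library. The series text also names a sleep restriction condition, which was not analysed here. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell, raw and not normalised, in 1 matrix of 31053 genes and 22204 barcodes. Per the file headers, the count matrix was written by Cell Ranger 6.0.2. The submitters' processing notes name Trimmomatic 0.39, Cell Ranger 4.0.0, Seurat 3.0, R 4.0.2 and the build GRCm38. Which of the 2 Cell Ranger versions set the counts could not be settled. How barcodes were called as cells is not given in the sources used here, and the lowest UMI count of a barcode was 500, 386 and 340 in the 3 libraries.

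The barcodes end in 1 of 3 numbers, read here as library 1, 2 and 3. No label ties an ending to a group. The libraries were therefore left unassigned, no group was compared with another, no library was taken as the control, and no order in time was read from the endings. What is given is each library's value, the spread over the 3 libraries as measured, and comparisons between cell classes within each library. With 1 library per group there would be no test in any case, so no p-value is given. Intervals are exact 95% binomial (Clopper-Pearson) intervals for shares of cells, exact Poisson intervals for summed UMIs, and exact conditional intervals for ratios. They cover counting error only, not differences between mice or between preparations. A gene at 0 UMIs in a library was set against a floor of 3 UMIs there. Its ratio is then a value against that floor and not a strict lower bound.

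Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs. Doublets were called with Scrublet per library, as implemented in scanpy 1.11.5, at an expected rate of 6%, and 553 of 18885 cells (2.93%) were left out. By library these were 1.71%, 3.09% and 4.25%, at automatic score thresholds of 0.332, 0.273 and 0.200 in libraries 1, 2 and 3. The doublets that remain may therefore differ between libraries, which was not tested. Kept cells were scaled to 10000 UMIs, log-transformed and clustered on 2000 variable genes without haemoglobin, mitochondrial, immunoglobulin and T cell receptor segment genes, Xist and Y genes. The clustering used 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1, with no integration of libraries. Clusters were named from marker lists fixed before the data were examined. The scoring of those markers was set after the data were seen. A marker counted when it was detected in at least 20% of a cluster's cells at a log2 fold of at least 0.5, and a name needed 3 such markers. Markers whose lowest cluster mean was at least 5% of the highest, among them the platelet genes Pf4 and Ppbp, were not used, and a type needed 50% of its markers usable. A cluster stayed unnamed when usable markers of another type outnumbered its own among its 10 leading genes, or when its median doublet score was at least 3 times that of all cells. The unnamed clusters held 1.90%, 2.50% and 2.09% of kept cells in libraries 1, 2 and 3. Class names carry the ending "-like" because they rest on RNA markers alone.

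Within each class and library raw UMIs were summed and given per 1000000 UMIs of that class and library (CPM). CPM are relative: in neutrophil-like cells S100a8 and S100a9 together took 12.8%, 26.5% and 31.2% of all UMIs in libraries 1, 2 and 3, which lowers every other gene's CPM. Scaling by the trimmed mean of M-values (TMM, edgeR 4.0.16) moved log2 values there by -0.48, 0.14 and 0.33. In monocyte-, B-, T- and NK-like cells it moved them by between -0.06 and 0.05. The fixed gene lists numbered 20. A list member was measured when it held at least 20 UMIs in the class or classes concerned. A list's deviation is the median, over its members, of log2 CPM in a library minus the mean over the 3 libraries. It is printed relative to the median of all measured genes of the class. For some lists in neutrophil-like cells its percentile among 10000 random lists matched on mean expression is given too, as a description of these libraries.

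The rule for named genes was written for comparisons against the control group, which could not be made. After the data were seen it was adapted to the spread over the libraries. Genes with at least 50 UMIs and 30 CPM in their highest library were ranked by the bound nearest 0 of the log2 ratio between the highest and the lowest library. Haemoglobin, mitochondrial, immunoglobulin and T cell receptor genes, Xist, Y genes and models without a gene name were excluded. Named were the first 16 in neutrophil-like cells and the first 6 each in monocyte-, B- and T-like cells, up to 4 members of each list, and 11 genes fixed beforehand in neutrophil-like cells. Genes named for the class comparisons are list members that were highest in the same class in all 3 libraries, chosen after their values were seen, as were the members named to show the opposite. NK-like cells numbered 82 in library 2, under the minimum of 100, so no spread over libraries is given for them.

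Alternatives planned before the data were examined were other cell filters, no removal of doublets, resolutions 0.5 and 2, shares of leukocytes only, classes from each cell's own UMIs, TMM and DESeq2 1.42.0 median-of-ratios scaling, totals without haemoglobin, mitochondrial and ribosomal protein genes, a minimum of 10 UMIs with no CPM minimum, means over cells, subtraction of free RNA, leaving out neutrophil-like clusters led by immature-neutrophil genes, and other list settings. Clustering without the list genes was added later. The counting statistics were tested on simulated class sums with the real mean profile and totals and 200 changed genes. In the simulation of neutrophil-like cells, run on 7715 genes, 96% of the intervals held the true ratio at each simulated fold, and 96.3% of the intervals of unchanged genes held 1. In monocyte-, B- and T-like cells, 90% to 100% of the intervals held the true ratio, lowest at a fold of 4 in monocyte-like and of 2 in B-like cells. The simulated counts were Poisson draws, and each ratio was of a fixed pair of libraries. The ratios used the totals the counts were drawn with. Such draws meet the assumptions of the intervals, so the result checks the computation only. The simulation therefore does not cover the choice of the highest and lowest library after the values were seen. Nor does it cover UMIs that are clumped in few cells, or a shift of the totals by abundant genes such as S100a8 and S100a9. Coordinates were matched by gene identifier to GENCODE M21 on GRCm38, where all 171 named genes were found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and R 4.3.3 were used.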

Results

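The data were UMI counts of single leukocytes from mouse blood, collected to follow their transcriptome under sleep deprivation. Each of the 3 libraries held the pooled leukocytes of 3 mice, and the 3 groups (Con at 0 h, SD24h and SD48h) had 1 library each. Libraries are numbered 1 to 3 by the ending of their barcodes. The labels do not say which number belongs to which group, so the effect of sleep deprivation was not estimated, and each library's value is given instead. Library 1 held 8815 barcodes and 40807434 UMIs, library 2 held 6648 and 30114546, and library 3 held 6741 and 36523283. The median barcode had 3987, 3722 and 4405 UMIs in libraries 1, 2 and 3, and its mitochondrial share was 6.65%, 1.03% and 4.32%. After filtering, 7000, 5793 and 5539 cells were kept, beside about 7000 cells planned per library.

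Neutrophil-like, monocyte-like, B-like, T-like and NK-like cells were present in every library, and their shares differed widely between libraries. Neutrophil-like cells made up 7.50% of kept cells in library 1 (95% interval 6.89 to 8.14), 54.4% in library 2 (53.1 to 55.7) and 34.7% in library 3 (33.4 to 36.0). B-like cells made up 60.0% (58.9 to 61.2), 23.8% (22.7 to 24.96) and 35.2% (33.9 to 36.4) in the same order. T-like cells ranged from 9.13% in library 2 to 17.7% in library 1, with a median of 14.6%, and NK-like cells from 1.42% to 4.36%, with a median of 2.82%. Monocyte-like cells ranged from 6.29% to 9.26%. The ratio of neutrophil-like cells to B-, T- and NK-like cells together was 0.0914 in library 1 (0.0834 to 0.0999), 1.58 in library 2 (1.49 to 1.67) and 0.660 in library 3 (0.623 to 0.699). These levels depended on the cell filter, and the mitochondrial share of a cell differs between classes. The median share in kept B-like cells was 6.92%, 6.31% and 6.02%, against 1.19%, 0.514% and 0.795% in neutrophil-like cells. With at least 500 genes and at most 5% mitochondrial UMIs per cell, the strict filter, the neutrophil-like share was 35.3%, 75.1% and 56.9%, and the ratio 0.858, 5.95 and 2.23. The 5% limit alone removed most B-like cells in every library, as their medians lay above it. The same holds for T-like cells, with medians of 5.96%, 5.45% and 5.35%. How much the limit of 500 genes added was not tested.

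**Figure D1:**
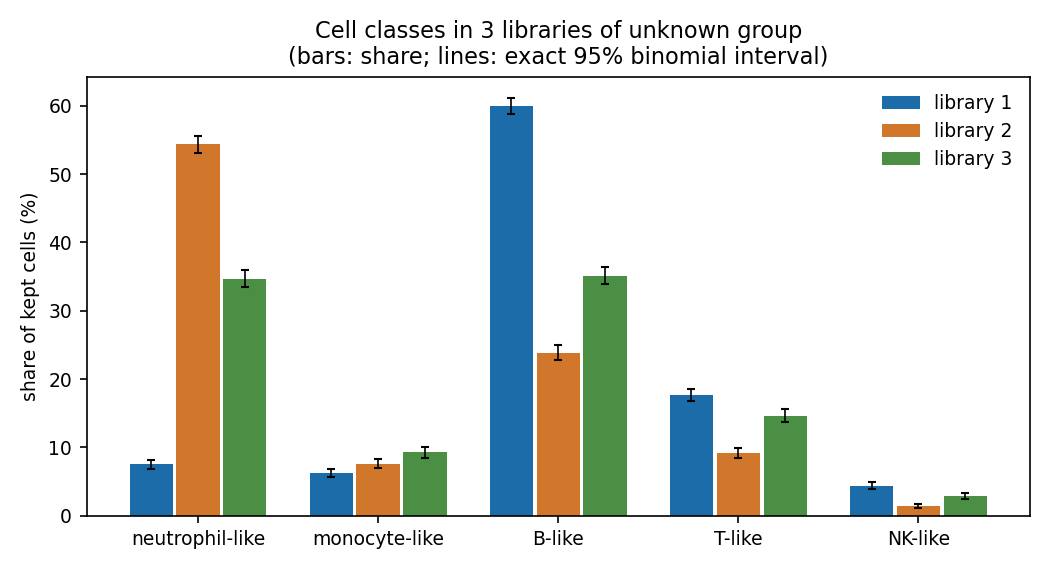
Share of kept cells (%, vertical axis) in 5 cell classes for libraries 1 to 3, whose groups are not known. Bars are shares and black lines exact 95% binomial intervals, which cover counting error only. The neutrophil-like share was 7.50%, 54.4% and 34.7%, and the B-like share 60.0%, 23.8% and 35.2%.

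The cytokine genes were divided between the classes, with interleukin-1 genes in neutrophil-like cells and interferon-gamma and 3 CCL chemokines in NK-like cells. Values are UMIs per 1000000 UMIs of a class and library (CPM). Of 21 measured members of the cytokine and chemokine list, 15 had their highest CPM in the same class in all 3 libraries, with intervals of the ratio to the next class that excluded 1. Neutrophil-like cells held 6 of these (Il1b, Il1rn, Il15, Osm, Csf1 and Ccl6), NK-like cells 4 (Ifng, Ccl3, Ccl4 and Ccl5), monocyte-like cells 3 (Il18, Tgfb1 and Ccl9) and B-like cells 2 (Lta and Ltb). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, stood at 2665, 2899 and 1255 CPM in neutrophil-like cells of libraries 1, 2 and 3, against 110, 301 and 145 CPM in monocyte-like cells and at most 17.8 CPM in B-like cells. Ifng stood at 69.2, 25.4 and 92.1 CPM in NK-like cells and at most 1.65 CPM in T-like cells. Ccl5, a chemokine of cytotoxic lymphocytes, reached 15028, 19350 and 16941 CPM in NK-like cells and 1168, 505 and 489 CPM in T-like cells. Tnf had no class with a clear lead in any library, at 12.1, 5.40 and 8.24 CPM in monocyte-like and 7.42, 5.05 and 6.01 CPM in neutrophil-like cells. No UMI of Il6 was found in neutrophil-like cells of any library. The floor of 3 UMIs there equals 2.02, 0.266 and 0.273 CPM in libraries 1, 2 and 3, which is not an upper bound of its level.

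The lists of neutrophil proteins followed the class names, with some members highest in monocyte-like cells. Among 13 measured genes of the S100 and calprotectin list, 11 were highest in neutrophil-like cells in all 3 libraries, S100a4 in monocyte-like cells and S100a10 in NK-like cells. Of 20 measured granule genes, 12 were highest in neutrophil-like cells, among them Mmp9 at 1785, 1741 and 2031 CPM, and 4 in monocyte-like cells, namely Prtn3, Chil3, Cybb and Lyz2. Of 18 measured migration and adhesion receptors, 12 were highest in neutrophil-like cells, such as Cxcr2, the receptor for neutrophil-attracting chemokines, and Csf3r, the receptor for granulocyte colony-stimulating factor. Of 23 oxidative burst and antioxidant genes, 6 were highest in neutrophil-like cells, 5 in monocyte-like cells and Txnrd1 in NK-like cells. Some of these genes are also cell type markers (S100a8, S100a9, Cxcr2, Csf3r and Mmp9 among them), so their place is not independent of the naming. When the clusters were made without any list gene, a setting added after the data were seen, 97.7% of kept cells stayed in their class. Clusters in that setting were still named with the full marker lists, so it does not remove the dependence on the naming. Over all lists together, 167 list genes had the same leading class in all 3 libraries, and 166 of them had the same class in that setting.

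MHC class II genes were mostly highest in B-like cells and cytotoxic genes in NK-like cells, and most MHC class I genes had no fixed class. All 10 measured MHC class II genes had a fixed leading class, 9 of them B-like cells and H2-DMb1 monocyte-like cells. Cd74, the invariant chain of MHC class II, stood at 13480, 14913 and 14913 CPM in B-like cells and at 2213, 2491 and 2066 CPM in monocyte-like cells. Of 12 measured cytotoxic effector genes, 11 were highest in NK-like cells, among them Gzma, which encodes granzyme A, at 10940, 12474 and 11232 CPM. Of 12 MHC class I genes, 2 had a fixed leading class (H2-K1 and H2-Q7, NK-like cells). Of the lymphocyte trafficking genes, the follicle-homing receptor Cxcr5 was highest in B-like cells, the lymph node homing receptor Ccr7 in T-like cells and S1pr5 in NK-like cells in all 3 libraries.

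Interferon-stimulated, stress and lipid mediator genes were spread over several classes. Of 28 interferon-stimulated genes, 10 were highest in neutrophil-like cells, 6 in monocyte-like cells and Gbp7 in NK-like cells. Of 17 measured genes of the prostaglandin and leukotriene pathway, Ptgs2 (cyclooxygenase-2), Alox5 and Alox5ap were highest in neutrophil-like cells, Pla2g4a and Hpgd in monocyte-like cells and Lta4h in NK-like cells. Ptgs2 was low, at 13.5, 6.82 and 1.37 CPM in neutrophil-like cells. Of 20 NF-kappaB targets, 5 were highest in B-like cells (Nfkb2, Rel, Relb, Birc3 and Cd83), 3 in neutrophil-like cells and Nfkb1 in monocyte-like cells. Of 22 immediate early and heat shock genes, 5 were highest in neutrophil-like cells, including Jun and Junb, 3 in monocyte-like cells, 2 in NK-like cells and Klf2 in B-like cells. Of 17 measured glucocorticoid-induced genes 8 had a fixed leading class, 5 of them neutrophil-like cells. Bhlhe40, in NK-like cells, was the only such gene of 15 measured circadian clock genes, and 3 of 16 apoptosis regulators (Mcl1, Fas and Bid, in neutrophil-like cells) and 2 of 19 cell cycle genes (Hmgb2 and Tubb5) had one. Of 13 mitochondrially encoded genes, 10 were highest in B-like cells. Of 10 haemoglobin and erythroid genes, 0 had a fixed leading class, and 5 of 10 platelet genes were highest in neutrophil-like cells.

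**Figure D2:**
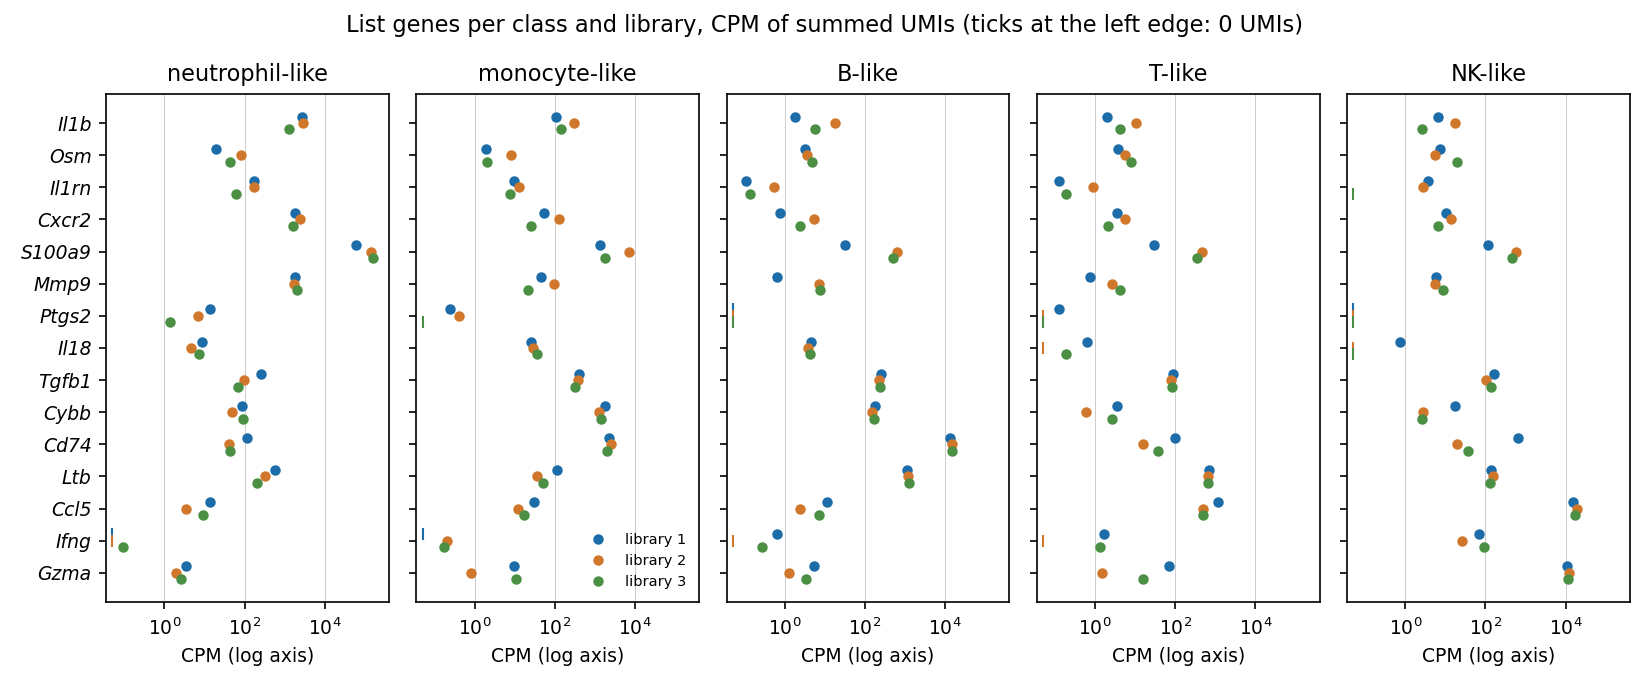
CPM of summed UMIs (horizontal log axes) of 15 list genes in 5 cell classes, with a dot per library and a tick at the left edge for 0 UMIs. Il1b stood at 2665, 2899 and 1255 CPM in neutrophil-like cells, and Ccl5 at 15028, 19350 and 16941 CPM in NK-like cells.

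Neutrophil-like cells of the 3 libraries differed in granule and S100 genes, and each library's neutrophil-like cells lay mostly in different clusters. In library 1, 509 of 525 were in a cluster led by Jaml, Lst1 and Cd101, which met 5 of its 18 markers. In library 2, 1510 and 1247 of 3150 were in clusters led by Clec4n and Fgl2 and by Mmp8 and Wfdc21. In library 3, 1467 of 1922 were in a cluster led by Ngp, Prok2 and Stfa2. The 16 genes with the widest spread were Prok2, Majin, Lipg, Ifitm6, Ggt1, Ly6g, Stfa2, Ltf, Igfbp6, Wfdc17, Acod1, Nos2, Acvrl1, Chil3, Cxcl2 and Upp1. Of these, 7 (Prok2, Lipg, Ifitm6, Ggt1, Ly6g, Stfa2 and Igfbp6) are themselves leading genes of those clusters, so their spread and the division into clusters are the same observation. The other 9 are not independent of that division either, as 509 of 525 neutrophil-like cells of library 1 were in 1 cluster. At resolution 2, Wfdc17 and Upp1 were leading genes of a neutrophil-like cluster with 1, 219 and 698 cells of libraries 1, 2 and 3. Ltf was one of another, with 1, 79 and 613 cells. Among these 9, Wfdc17 stood at 824, 11062 and 14184 CPM in libraries 1, 2 and 3, 17.2 times apart (16.3 to 18.2). With TMM scaling, ratios of libraries 2 and 3 to library 1 in these cells are higher, the log2 ratio of Wfdc17 being 4.92 beside 4.11. Cxcl2, a neutrophil-attracting chemokine, had 1, 448 and 575 UMIs, or 0.675, 39.7 and 52.3 CPM. Acod1, which makes itaconate, stood at 4.05, 143 and 94.7 CPM. Nos2, the inducible nitric oxide synthase, had 0 UMIs in library 1 and 40.0 CPM in library 3. The latter is 19.7 times the floor of 3 UMIs in library 1 (2.02 CPM). Majin, a gene of meiosis, was ordered the other way, at 44.5 CPM in library 1, 11.4 in library 2 and 0 UMIs in library 3.

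Of the genes fixed beforehand, S100a8 and S100a9, the subunits of calprotectin, were the most abundant. S100a8 stood at 65331, 117738 and 146874 CPM and S100a9 at 62188, 147472 and 164818 CPM. With TMM scaling they stood at 47000, 129816 and 185163 and at 44739, 162600 and 207786 per 1000000 scaled UMIs. Cxcr2 stood at 1827, 2483 and 1603 CPM and Cxcr4, a receptor for bone marrow retention, at 372, 241 and 138 CPM. Among glucocorticoid targets, Tsc22d3 stood at 412, 609 and 452 CPM and Fkbp5 at 17.5, 29.8 and 20.8 CPM. The total used for scaling decided part of this order. With TMM scaling, Cxcr2 stood at 1314, 2738 and 2021 and Tsc22d3 at 297, 671 and 570 per 1000000 scaled UMIs, so that library 1 and not library 3 was the lowest for Cxcr2, and Cxcr4 stood at 268, 266 and 174. The interval of the highest to lowest ratio of Tnf, 1.47 (0.695 to 2.83), held 1. Il1b was 2.31 times apart between libraries 2 and 3 (2.26 to 2.36), but without the cluster led by immature-neutrophil genes that log2 ratio was -0.02. That cluster, led by Ngp, Prok2 and Stfa2, held 4 of 525, 376 of 3150 and 1467 of 1922 neutrophil-like cells in libraries 1, 2 and 3. Leaving it out thus removes most of this class in library 3. On GRCm38, Il1b lies on chromosome 2 (129364570 to 129371139, minus strand), S100a8 on chromosome 3 (90668978 to 90670035, plus strand) and S100a9 on chromosome 3 (90692632 to 90695721, minus strand). All are annotated as protein-coding in GENCODE M21.

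Relative to all measured genes of the class, the median of 18 granule genes deviated by -1.47, 0.21 and 1.18 on the log2 scale in libraries 1, 2 and 3 (percentiles 0, 95.4 and 100 among random lists). Highest values at least 1.5 times the lowest were reached by 15 of the 18, of which 12 were highest in library 3. The 13 S100 and calprotectin genes deviated by -1.08, 0.10 and 0.78, and the 27 measured interferon-stimulated genes by -0.75, -0.00 and 0.65 (percentiles 0, 12.8 and 100). Ifitm1, of the latter list, stood at 943, 6304 and 9572 CPM. The 16 glucocorticoid-induced genes deviated by -0.51, 0.32 and 0.19, with Il1r2, a decoy receptor for interleukin-1, at 130, 644 and 587 CPM. The cytokine list deviated by -0.09, 0.40 and -0.04 (percentiles 43.3, 100 and 29.7) and the 18 migration and adhesion receptors by -0.28, 0.31 and -0.01. Circadian clock genes, of which 7 were measured, deviated by -0.28, 0.49 and -0.24 (percentiles 17.2, 99.2 and 8.14), but the 4 members with at least 100 UMIs were at percentiles 2.17, 99.8 and 90.7. Medians lay between -0.17 and 0.30 in every library for NF-kappaB targets, the prostaglandin pathway, immediate early genes, oxidative burst genes, MHC class I, lymphocyte trafficking, apoptosis and the 4 measured cell cycle genes. The highest of these, 0.30 for immediate early genes in library 2, was at percentile 99.9. The 9 MHC class II genes deviated by 0.98, -0.77 and -0.16, and the 4 measured cytotoxic genes by 0.35, -0.57 and 0.23. As measures of other RNA in the same cells, platelet genes deviated by 0.79, -0.46 and -0.28, mitochondrially encoded genes by 0.28, -0.48 and 0.19, and haemoglobin and erythroid genes by -0.60, 0.23 and 0.24. The B-cell gene Igkc stood at 139, 36.9 and 48.6 CPM there, and at 11680, 12340 and 12514 CPM in B-like cells.

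**Figure D3:**
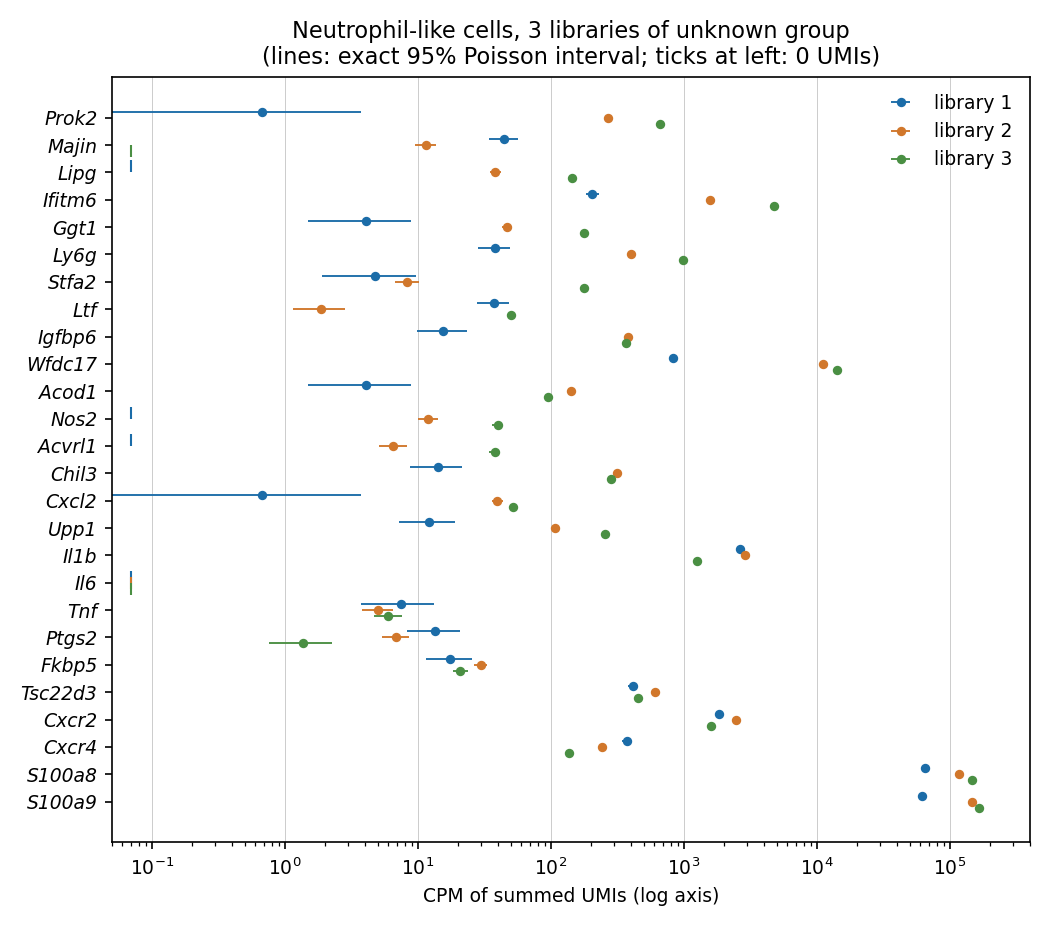
CPM of summed UMIs (horizontal log axis) in neutrophil-like cells of libraries 1 to 3, for the 16 genes with the widest spread and the 11 genes fixed beforehand (Cxcl2 is in both and is drawn once). Dots are values, lines exact 95% Poisson intervals and ticks at the left 0 UMIs. S100a9 stood at 62188, 147472 and 164818 CPM.

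In monocyte-like cells the 6 genes with the widest spread were Saa3, Lrg1, C1qb, Igfbp6, Aldh1l1 and Prok2. The class mixes subsets that differ by library: at resolution 2, a cluster led by Chil3, Vcan and Saa3, among others, held 9, 331 and 257 cells of libraries 1, 2 and 3, and a cluster led by Cd209a held 236, 37 and 25. Under the strict filter the Cd209a-led cluster was left unnamed, with 163, 38 and 26 cells. Saa3, an acute-phase serum amyloid gene, had 1, 1011 and 4177 UMIs in libraries 1, 2 and 3, or 0.247, 210 and 703 CPM, and is itself a leading gene of a monocyte-like cluster. Lrg1 stood at 11.6, 177 and 263 CPM and C1qb, a complement component, at 2.71, 38.6 and 84.3 CPM, in 3, 16 and 45 cells. Prok2 stood at 0, 36.3 and 2.52 CPM, in 0, 19 and 11 cells, and 1 cell held 16% of its UMIs in library 2. Igfbp6 stood at 0.247, 66.8 and 59.9 CPM, but without the list genes in the clustering its log2 ratio between the same libraries was -0.55. Prok2 and Igfbp6 are also leading genes of neutrophil-like clusters. Glucocorticoid-induced genes deviated by -0.49, 0.20 and 0.17, with the metallothionein Mt1 at 6.41, 29.9 and 67.3 CPM. Interferon-stimulated genes deviated by 0.09, -0.01 and -0.06. Neutrophil granule genes deviated by -0.95, 0.46 and 0.30 and S100 genes by -0.86, 0.68 and 0.22 in this class, and S100a8 there stood at 1449, 6319 and 2677 CPM. Of other RNA, Igkc stood at 527, 61.8 and 63.9 CPM in monocyte-like cells, and platelet genes deviated by 0.95, -0.41 and -0.54. Haemoglobin and erythroid genes deviated by 0.43, 0.16 and -0.67, and the 5 measured cytotoxic genes by 0.71, -1.21 and 0.19. In library 1 the cell with the most UMIs of each gene held 59.1% of Hbb-bt, 40.8% of Hbb-bs and 45.4% of Hba-a2.

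In B-like cells the widest spreads belonged largely to genes of neutrophils and to a single cell. S100a8 stood at 29.3, 412 and 349 CPM, S100a9 at 32.3, 621 and 490 CPM, Retnlg at 2.88, 52.5 and 87.4 CPM and Ifitm1 at 1.65, 32.9 and 33.6 CPM. These genes were highest in neutrophil-like cells, and at like levels in T-like cells, where S100a8 stood at 28.0, 293 and 258 CPM. Jchain, a plasma cell gene, stood at 33.2, 0.726 and 0.131 CPM, but 96.0% of its UMIs in library 1 came from 1 cell. Ddit4, a stress gene that glucocorticoids induce, stood at 8.57, 49.9 and 45.7 CPM, 5.82 times apart (4.78 to 7.12). The glucocorticoid list of 13 measured genes deviated by -0.69, 0.25 and 0.33. The 28 interferon-stimulated genes deviated by -0.49, -0.09 and 0.54, with 22 of the 23 members that spread by at least 1.5 times highest in library 3. A B-like cluster led by Ifit3, Usp18 and other interferon-stimulated genes held 1.52%, 3.69% and 4.21% of the B-like cells. MHC class II genes deviated by -0.06, 0.01 and 0.05, and 0 of 10 spread by 1.5 times. Of other RNA in B-like cells, platelet genes deviated by 0.73, -0.59 and -0.15, and haemoglobin and erythroid genes by 0.32, -0.64 and 0.14. The 7 measured cytotoxic genes deviated by 0.68, -0.69 and 0.12, and the 10 measured granule genes by -1.58, 0.63 and 0.90.

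In T-like cells the glucocorticoid-induced and interferon-stimulated lists were lowest in library 1, as in B-like cells. Ddit4 stood at 11.95, 63.6 and 61.7 CPM, and the 12 measured glucocorticoid-induced genes deviated by -0.45, 0.33 and 0.08. The 28 interferon-stimulated genes deviated by -0.32, -0.06 and 0.45, with Ifit3 at 14.8, 15.9 and 52.3 CPM and 18 of 19 members that spread by 1.5 times highest in library 3. Junb stood at 72.4, 202 and 184 CPM. The 8 measured granule genes deviated by -1.04, 0.43 and 0.69 in T-like cells, and so were lowest in library 1 as well. Of the glucocorticoid-induced list 5 members, and of the interferon-stimulated list 10, were highest in neutrophil-like cells in all 3 libraries. The list values were not recomputed after subtraction of free RNA. How far RNA of neutrophils accounts for them in T- and B-like cells was not tested. Among the first 6 genes, S100a8, S100a9 and Retnlg are those named above for B-like cells. Ptn had all of its 387 UMIs in 1 cell of library 1, 99.5% of the Igfbp6 UMIs of library 1 came from 1 cell, and 28.4% of the Gzma UMIs did. The MHC class II genes deviated by 1.10, -1.06 and -0.04 in T-like cells, with Cd74 at 101, 15.3 and 36.1 CPM. The B-cell gene Igkc stood at 138, 24.4 and 42.5 CPM there. Haemoglobin and erythroid genes in T-like cells deviated by -1.06, 0.06 and 0.99, with Hbb-bs at 235, 1178 and 2243 CPM, in the same order as the interferon-stimulated genes, and 1 cell of library 3 held 20.1% of its Hbb-bs UMIs.

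Summed over all kept cells, values followed the cell shares as well as the levels within classes. S100a8 stood at 3128, 52644 and 52291 CPM, Il1b at 135, 1326 and 474 CPM and Cxcr2 at 91.2, 1113 and 572 CPM. For Il1b the highest library was 9.81 times the lowest over all cells (library 2 over library 1), beside 2.31 times within neutrophil-like cells, where the pair was library 2 over library 3. Without the cluster led by immature-neutrophil genes, the log2 ratio of that pair within the class was -0.02.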

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

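Of the alternatives, the clustering without list genes was chosen only after the data were seen. In every setting the neutrophil-like share and its ratio to lymphocyte-like cells were lowest in library 1 and highest in library 2. The log2 ratio of the highest to the lowest library kept its sign for 66 of 67 gene values under TMM and under median-of-ratios scaling, where Tnf in neutrophil-like cells gave -0.06 under both, inside the interval of its own value. It kept its sign for all 67 with totals without haemoglobin, mitochondrial and ribosomal protein genes, all 66 under the strict filter and all 60 as means over cells. Apart from the genes fixed beforehand, these genes were chosen for a wide spread, so a change of sign was unlikely from the start. TMM moved 25 values beyond their intervals, the strict filter 22, and 23 of 39 moved without clusters led by immature-neutrophil genes. That last setting left out 1467 of the 1922 neutrophil-like cells of library 3, but 376 of 3150 in library 2 and 4 of 525 in library 1. Of the 167 list genes highest in the same class in all 3 libraries, 120 were shared under the strict filter (125 in all), 164 with doublets kept, 166 without list genes and 161 after free RNA was subtracted. Of the 16 genes of widest spread in neutrophil-like cells, 14 were shared with a minimum of 10 UMIs and no CPM minimum. The number of cells limits NK-like cells, with 82 cells in library 2. No paired analysis was possible because each group has 1 library.

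With at least 500 genes and at most 5% mitochondrial UMIs, the strict filter, the neutrophil-like share was 35.3%, 75.1% and 56.9% in libraries 1, 2 and 3 and the ratio 0.858, 5.95 and 2.23. In library 1, with cells clustered and named anew, it gave 514 neutrophil-like and 599 lymphocyte-like cells, beside 525 and 5747. With no cell filter the share was 6.38%, 50.2% and 30.8% and the ratio 0.0771, 1.36 and 0.580. Classes from each cell's own UMIs gave shares of 8.17%, 57.1% and 36.4% and a ratio of 0.100 in library 1. Resolution 2 gave ratios of 0.104, 1.81 and 0.735. There, clusters of 745 and 737 cells with B-cell markers were left unnamed, which took them out of the lymphocyte-like cells. In library 1 the neutrophil-like cells still numbered 525, while the B-like share was 49.4% and the unnamed share 12.1%. In library 2 the share was 56.5% at resolution 0.5 and 56.4% without list genes. The strict filter sets 2 limits at once, and they were not applied separately. Its 5% limit alone removed most B- and T-like cells, whose median mitochondrial shares lay above it in every library. In the settings other than the strict filter and resolution 2 the cause was not tested. The shares of the other classes moved beyond their intervals in some settings as well.

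Signs were the other way for Igfbp6 in monocyte-like cells without list genes (-0.55), for Igfbp6 in T-like cells with doublets kept (-5.09) and without list genes (-1.89), for Ifitm1 in monocyte-like cells after free RNA was subtracted (-1.53) and for Il1b in neutrophil-like cells without clusters led by immature-neutrophil genes (-0.022). For Igfbp6 in T-like cells, 1 cell held 99.5% of the UMIs of library 1. For the others the cause was not tested. The subtraction took 42.8% of the monocyte-like UMIs of library 1 but at most 4.27% in other classes, so its values in monocyte-like cells are not a correction to rely on. The haemoglobin list in neutrophil-like cells of library 1, before the median of all genes is taken off, deviated by -0.19, and by 0.12 with members of at least 100 UMIs, by construction a different set of genes.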

Other observations

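All tests below were chosen after the patterns were seen, and that of the cell filter only after its own result was seen. What each other test would show was written down before it was run, with 1 change made before any value was computed. The Clec1b to Pf4 test was first worded with B-like cells split by Pf4 and was run with the split by Ppbp, because a split by a gene of the ratio biases it. No biological explanation was tested for any pattern, because no library was tied to a group.

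B-like clusters differed between libraries. At resolution 1 the cluster led by Fcer2a, Fchsd2 and Fcmr held 1974, 191 and 348 cells of libraries 1, 2 and 3, or 47.0%, 13.8% and 17.9% of the B-like cells. At resolution 0.5 a cluster led by platelet genes (Gp5, Treml1, Itga2b and Ppbp among them) held 1241, 90 and 213 cells, or 29.1%, 6.41% and 10.7%. It met 15 of 15 B-cell markers and was named by them, as platelet markers were not used for naming. An unnamed cluster led by Nid1, Bhlhe41 and Zbtb20 held 63, 22 and 48 cells, which is 1.499, 1.59 and 2.47 per 100 B-like cells.

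The values of the 3 libraries lay apart for the neutrophil-like share (7.50%, 54.4% and 34.7%), with no overlap of their counting intervals. The cell filter did not make this difference, since without it the share of library 1 was 6.38%, against 30.8% in library 3. Of 554 neutrophil-like cells of library 1 without the filter, 11 (1.99%, 0.995 to 3.52) held under 1000 UMIs, 2 times the lowest barcode. Few called cells thus lay near the lowest barcode. Cells that were not called cannot be counted, and the calling rule is not known, so the test cannot exclude their loss. Loss of shallow cells at cell calling, loss of neutrophils before capture, differences between the pooled mice and the groups themselves stay open.

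Neutrophil-like cells mixed less between the 3 libraries than other classes did. In balanced draws of 80 cells per library, a median of 79.7% of the 15 nearest neighbours of a neutrophil-like cell came from its own library, against 60.4% in monocyte-like, 41.4% in B-like, 40.7% in T-like and 39.8% in NK-like cells. The highest draw in any of these classes, 66.6%, was below the lowest in neutrophil-like cells, 75.7%, so the ranges did not overlap. This cannot exclude a shift that moves every class alike, because the same shift separates a less varied class more. With every cell thinned to 1000 UMIs (77, 158 and 122 shallower cells left out) the value in neutrophil-like cells was 73.5%. Its lowest draw, 69.6%, was above the highest in T-like cells, 43.1%, so unequal depth alone does not account for the difference. A shift common to all classes, a technical effect on neutrophils alone, such as the time to processing, and the groups themselves stay open.

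Platelet genes were seen in every class, and in neutrophil-, monocyte-, B- and T-like cells 10 of 10 were highest in library 1, with a mean of 18.5, 7.02 and 8.83 platelet-gene UMIs per B-like cell in libraries 1, 2 and 3. Free RNA alone, spread evenly over droplets of equal depth, would give a Fano factor (variance over mean) near 1. In B-like cells it was 13.1, 10.2 and 15.6 in libraries 1, 2 and 3, each above the bound set beforehand. These values argue only against free RNA spread evenly over droplets of equal depth. UMIs were not adjusted for the depth of each cell, and unequal depth also raises the factor, by an amount that was not tested. Of the B-like cells, 0.357%, 9.41% and 7.81% held no platelet-gene UMI in libraries 1, 2 and 3. Haemoglobin genes in the same cells gave 732, 2.93 and 166, so a value above 1 alone does not tell platelet RNA apart from RNA of other blood cells, and in libraries 1 and 3 haemoglobin gives no lower baseline. The Clec1b to Pf4 ratio was higher in B-like cells with the most Ppbp than in those with the fewest by 1.60 (1.48 to 1.73), 1.36 (1.149 to 1.62) and 1.68 (1.47 to 1.93) times, and the lowest, 1.36, lay between the bounds set beforehand, so the test cannot tell whether a single source with 1 ratio of its genes accounts for it. Platelets attached to leukocytes or caught in the same droplet remain possible and were not tested directly.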
